A study of Caenorhabditis elegans with 2 samples.

How the data were processed

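The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of REC-8, a meiosis-specific kleisin subunit of the cohesin ring, in Caenorhabditis elegans. Per the labels, the worms stably expressed REC-8 with a C-terminal GFP-FLAG tag, and chromatin was sheared by sonication and precipitated with an antibody against GFP. A further label gives the antibody as rec-8, and the description, which names GFP, was followed here. Whole hermaphrodites were taken as young adults 48 hours after synchronization at the starved L1 stage. There was 1 group of 2 biological replicates. A control file went into the authors' peak calls, per the notes deposited with the files, but no control library was analysed here, so no comparison between groups was made.

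The authors deposited peak lists in the narrowPeak format, on the ce11 and the ce10 genome builds. Each replicate had a relaxed list of peaks and background made as input for a reproducibility analysis (the irreproducible discovery rate, IDR). The reads of both replicates together had another relaxed list, and a reproducible set had been chosen from it by IDR. In each list the deposited signal column holds the value that the authors' peak caller gave a peak, and how the control entered it is not given in the sources used here. The deposited q-value column is on a −log10 scale and reached 2.37 in the reproducible set. A further deposited column places the summit within the peak. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The files hold no read counts, so the depth of each library is unknown, and the signal is the authors' own value for each peak. Signal was used only to rank or describe peaks within a list.

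All main results used the ce11 files with the WBcel235 genome, which is the same assembly, and the gene annotation of Ensembl release 115. Of the ce11 peaks, 0 ended past the end of a WBcel235 chromosome. RNA gene names came from the RefSeq annotation of the same assembly, matched by WormBase gene identifier for 46881 of 46926 genes, and mitochondrial genes by position. The ce10 files were used on their own positions, with no conversion. No ce10 genome was used, so the ce11 chromosome lengths stood in for them. Scripts were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were made with matplotlib 3.10.9.

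The main tests, the 29 gene lists, the 6 sequence motifs and the rule for named genes were fixed before the data were examined. Each summit was placed in 1 class, in the order within 500 bp of a protein-coding transcript start, within 500 bp of a non-coding RNA gene other than a piRNA gene, exon, intron and intergenic. Counts were set beside 1000 random rotations of the peaks along each chromosome, with a two-sided permutation p. A gene was at a peak when a summit lay within 500 bp of the start of any of its transcripts. Starts are the annotated ones, which in worms are often sites of trans-splicing and not of the start of transcription. The shares of the lists were compared by two-sided Fisher's exact tests. Protein-coding lists were set against the other protein-coding genes, and RNA gene lists against all other genes. Peaks per nuclear chromosome and in the central part of each chromosome (33.3% of its length) were tested by exact two-sided binomial tests. GC content was taken in 200 bp around each summit and in flanks 1000 bp to each side, with a sign-flip permutation test of 100000 resamples. Motif matches on either strand were compared with the left flank by exact McNemar tests. The right flank was added as a control after the data were seen. Adjusted p-values are Benjamini-Hochberg values over the 6 chromosomes, the 29 lists or the 6 motifs. Intervals are exact 95% binomial (Clopper-Pearson) intervals unless named otherwise, and they cover the counting of peaks or genes only. Peaks and genes were the units of every test, not animals. Neighbouring genes can share a peak, so the p-values can be smaller than independent units would give. The main counts were also taken from the 606 top peaks by signal of each replicate alone.

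The named genes were the nearest gene to each of the 20 peaks of highest signal, up to 3 members of highest signal from each list with a member at a peak, and rec-8 and unc-119. Since 19 of those 20 peaks lay on mitochondrial DNA, the genes at the 20 nuclear peaks of highest signal were added after the values were seen. The alternatives were the 303 reproducible peaks of higher signal, each replicate alone, the ce10 files, windows of 250 and 1000 bp, other ways to match peaks and other expectations. The scripts were tested on a simulated reproducible set and simulated replicate lists of 606 peaks each. In these 200 peaks were put at tRNA genes, 400 peaks were shared by the replicates, and the remaining peaks lay at random positions. The tRNA list was recovered, with 239 genes at a simulated peak, and 0 of 23 protein-coding lists with no simulated effect were called. The 400 shared peaks were matched, which the simulation fixed in advance, as its replicate lists were far shorter than the real ones. Real peaks favour gene starts, so the simulation does not show how often a list would be called by chance on them. Of the other RNA lists 1 was called, the piRNA genes, although no effect had been simulated for them. Of the 6 motifs 3 were called on these peaks, the B box core, the GC box and the GA repeat.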

Results

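REC-8::GFP binding was profiled by ChIP-seq in whole young adult hermaphrodites of C. elegans, in 2 biological replicates. REC-8 is a cohesin subunit that helps to hold sister chromatids together in meiosis, and it acts in the germ line of these animals. The reproducible set held 606 peaks on ce11, of which 584 lay on the nuclear chromosomes and 22 on mitochondrial DNA. Their median width was 430 bp (range 108 to 2137). The relaxed lists held 21160 peaks for replicate 1, 21503 for replicate 2 and 18953 for both together. The depth of the libraries is unknown, because the files give no read counts. The samples form 1 group, so the questions addressed here are where on the chromosomes, at which genes and at which sequences the peaks lay.

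REC-8::GFP summits lay close to gene starts, and above all at genes for non-coding RNAs. A non-coding RNA gene was within 500 bp of 265 summits (43.7%) that had no protein-coding start as near, against a mean of 42.3 ± 6.27 (SD) in 1000 rotations, which is 6.27 times as many. Another 260 summits (42.9%) lay within 500 bp of a protein-coding transcript start, 1.77 times the rotated mean of 146.5 ± 10.3. With RNA genes counted first, an order chosen after the data were seen, 163 summits (26.9%) were at protein-coding starts, a ratio of 1.33, and 362 (59.7%) at RNA genes, a ratio of 5.46. Exons away from starts held 18 summits, where rotations gave 117.4, and introns also held 18, where rotations gave 143.2. Intergenic sequence held 45 summits against 156.6. With protein-coding starts counted first, no rotation lay as far from the rotated mean as any count, with a two-sided permutation p of 0.001. That is the smallest p that 1000 rotations can give. With RNA genes counted first, the permutation p was 0.001 for RNA genes and 0.002 for protein-coding starts. The top 606 peaks of replicate 1 put 258 summits at non-coding RNA genes and 231 at protein-coding starts, and those of replicate 2 put 242 and 293 there.

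**Figure D1:**
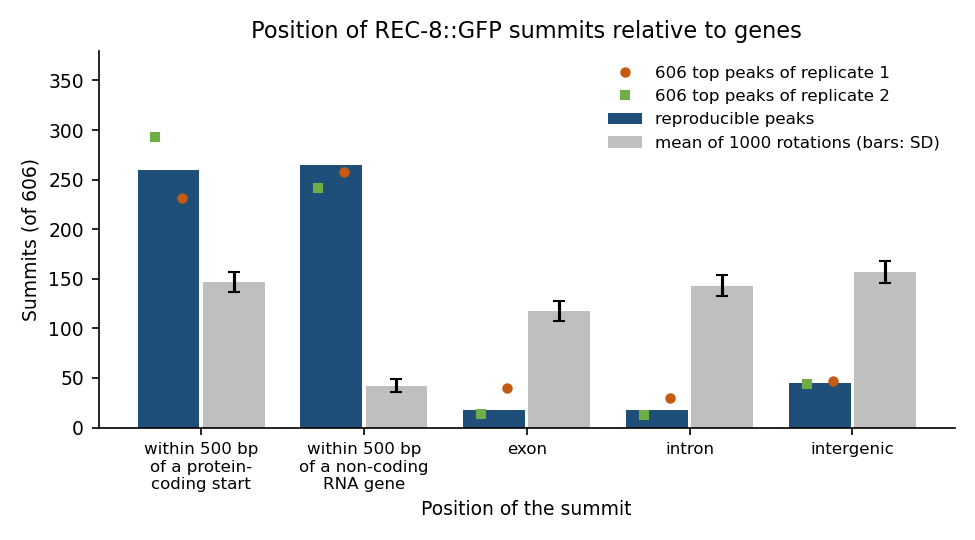
Number of the 606 reproducible summits in each position class (dark bars) and the mean of 1000 rotations along the chromosomes (grey bars, with SD), with the top peaks of each replicate alone as points. The 265 summits at non-coding RNA genes stand against a rotated mean of 42.3, while exons and introns hold 18 summits each.

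Transfer RNA genes were the class most often at a peak. Of 634 annotated tRNA genes, 291 (45.9%, interval 42.0 to 49.9) had a summit within 500 bp of their start, against 694 of the 46292 other genes. The ratio was 30.6 and the adjusted p from Fisher's exact test 1.00e-321. The other genes include 15363 piRNA genes, of which only 15 were at a peak. This raises the ratio here and those of the snoRNA and snRNA genes below. Against random positions on the nuclear chromosomes, by rotations chosen after the data were seen, the ratio was 67.4 for tRNA genes and 34.2 for snoRNA genes. With mitochondrial DNA included it was 13.0 for tRNA genes, as peaks cover most of that molecule however they are rotated. On the nuclear chromosomes alone, a restriction chosen after the data were seen, 272 of 612 tRNA genes (44.4%) were at a peak. In all, 234 of the 584 nuclear summits (40.1%) had a tRNA gene start within 500 bp, where rotations gave a mean of 3.59, and their median distance to it was 41.5 bp. The top peaks of replicate 1 touched 273 tRNA genes and those of replicate 2 touched 265. Genes at the strongest of these nuclear peaks were M02F4.t1, a glycine tRNA gene (X:3036092-3036208, signal 272.9), and C04A11.t1, a leucine tRNA gene (X:13665468-13665683, signal 251.7). T09B4.t1, an isoleucine tRNA gene (I:6164164-6164278, signal 248.8), followed. Next came the alanine tRNA genes F15G9.t1 and F15G9.t2 at a shared peak (signal 248.4), the genes T23F1.t1 (lysine) and T23F1.t2 (proline) at another (signal 242.7), and R04D3.t2 (valine, signal 238.4). The gene nearest to the summit was an unclassed ncRNA gene at both shared peaks, F15G9.8 and T23F1.9. At the peak of highest signal of this list, on mitochondrial DNA, lay tRNA-Phe, tRNA-Gln, tRNA-Arg and tRNA-Ile, which shared the 1 peak. The nuclear genes were chosen after their values were seen, by their place among the 20 nuclear peaks of highest signal.

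Small nucleolar RNA genes, whose RNAs guide chemical changes of ribosomal RNA, were at a peak in 66 of 346 cases (19.1%, interval 15.1 to 23.6). The ratio to other genes was 9.67 (adjusted p = 7.52e-42, Fisher's exact test). They held the strongest nuclear peaks. The peak of highest nuclear signal (421.4, V:8500410-8500717) had its summit 16 bp from the start of the snoRNA gene ZK994.7 and ranked 19 in replicate 1 and 20 in replicate 2. The next 2 nuclear peaks lay at the neighbouring snoRNA genes C51F7.3 and C51F7.4 (V:12303482-12303745, signal 336.9) and at W03C9.9 (II:11960681-11960989, signal 333.3). Further snoRNA genes among the 20 nuclear peaks of highest signal were ZK265.10, ZK484.9, Y75B12B.12, T03F7.8 and T06C12.16. Small nuclear RNA genes were at a peak in 10 of 129 cases (7.75%, ratio 3.72, adjusted p = 0.00199, Fisher's exact test). They were led by W05B2.8 (III:10989564-10989791, signal 251.7) and by sls-2.4 (signal 215.5) and sls-2.1 (signal 177.9), which encode the SL2 leader RNA joined to messenger RNAs by trans-splicing. The gene rpr-1, which encodes the RNA of ribonuclease P, the enzyme that trims tRNA precursors, held a peak of signal 264.4 (I:13463836-13464101). Unclassed ncRNA genes lay within 500 bp of 219 of the 584 nuclear summits, where rotations gave a mean of 39.1 (permutation p = 0.001, the smallest possible), but only 29 of these summits had no tRNA, snoRNA, snRNA, rRNA or microRNA gene within 500 bp.

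The lists of ribosomal RNA, microRNA and piRNA genes were not at peaks more often than other genes by the test. Ribosomal RNA genes were at a peak in 2 of 22 cases (adjusted p = 0.224, Fisher's exact test), both of them the mitochondrial rRNA genes s-rRNA and l-rRNA, while none of the 20 nuclear ones was (interval 0 to 16.8%). MicroRNA genes were at a peak in 4 of 261 cases (1.53%, adjusted p = 0.968, Fisher's exact test), with mir-4936, mir-51 and mir-58.1 at those of highest signal. The genes for piRNAs, the small RNAs that silence foreign sequence in the germ line, were at a peak in 15 of 15363 cases (0.0976%, ratio 0.0318, adjusted p = 5.97e-143, Fisher's exact test). They included 21ur-53, 21ur-763 and 21ur-5229, and the summits near 10 of the 15 also had a tRNA gene within 500 bp. Rotations gave a mean of 91.0 piRNA genes at a peak (adjusted permutation p = 0.01). The same Fisher's test called piRNA genes on simulated peaks that had no such effect, so the size of this deficit is better read from the rotations.

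Among protein-coding genes, 320 of 19985 (1.60%) were at a peak, and the genes of the cytosolic ribosome stood out. Of 81 ribosomal protein genes 14 (17.3%, interval 9.78 to 27.3) were at a peak, against 1.54% of other protein-coding genes (ratio 11.2, adjusted p = 2.76e-10, Fisher's exact test). The highest signals were at rpl-3 (288.9, III:3867444-3867706), rpl-15 (222.1, IV:654823-655025) and rpl-35 (203.9, III:7854643-7854776). The summits lay a median of 329 bp from the nearest annotated start, and with a window of 250 bp the ratio was 2.72 (adjusted p = 0.41, Fisher's exact test). Of the 64 ribosomal protein genes with no tRNA, snoRNA or snRNA gene within 1000 bp, a restriction chosen after the data were seen, 10 (15.6%) were at a peak. Top peaks of replicate 1 touched 11 of the 81 genes, those of replicate 2 touched 13. Chemoreceptor genes, large families used in sensory neurons, were at a peak in only 2 of 1293 cases (0.155%, ratio 0.0909, adjusted p = 1.34e-06, Fisher's exact test). Those were srd-44 and srh-269, and both summits also had a tRNA gene within 500 bp. Against rotations, which compare the list with random positions and not with other genes, the chemoreceptor deficit did not pass the test (2 against a mean of 5.91, adjusted permutation p = 0.276).

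**Figure D2:**
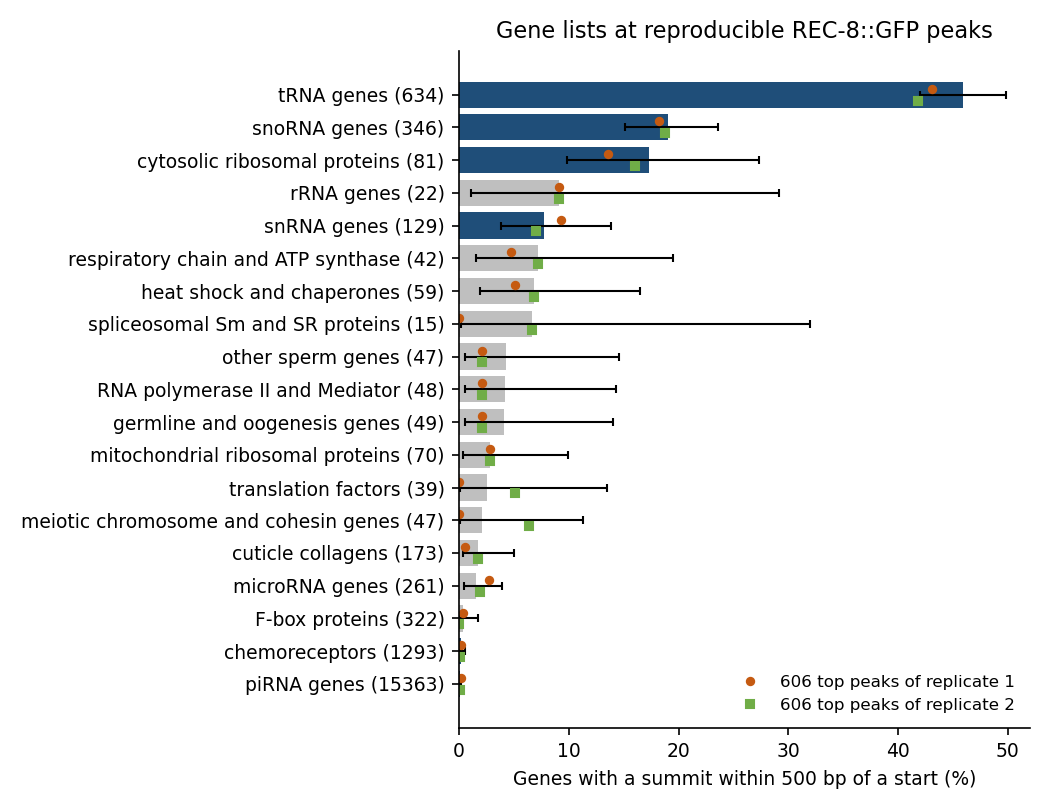
Share of each gene list (number of genes in brackets) with a reproducible summit within 500 bp of a start, for the 19 lists with any gene at a peak. Bars give the percent with its exact 95% interval and are dark where the list passed the test in either direction, and points give the top 606 peaks of each replicate alone, with tRNA genes at 45.9% at the head and piRNA genes at 0.0976% at the foot.

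The remaining 21 protein-coding lists did not pass the test. The meiotic chromosome and cohesin list had 1 of 47 genes at a peak, him-5, a gene needed for crossing over on X. That summit lay past the annotated 3′ end of him-5, 421 bp from its nearest transcript start, and within 500 bp of a snoRNA gene. With outermost 5' ends only, 0 of the 47 genes were at a peak. The germline list had 2 of 49 genes (puf-11 and spn-4, both for RNA-binding proteins), and the list of other sperm genes had 2 of 47 (spe-48 and spe-39). The genes spn-4 and spe-39 are neighbours and shared 1 peak. Respiratory chain and ATP synthase genes had 3 of 42 (7.14%, adjusted p = 0.107, Fisher's exact test), namely atp-5, cox-5A and cox-5B. Heat shock and chaperone genes had 4 of 59 (6.78%, adjusted p = 0.061, Fisher's exact test), with hsp-90, cct-8 and dnj-29 at the highest signals. Against rotations both lists passed, with adjusted permutation p of 0.012 for the respiratory genes and 0.006 for the chaperones. Rotations compare a list with random positions, and summits at protein-coding starts of all kinds were 1.77 times the rotated mean. Passing there thus does not show a difference from other protein-coding genes. Mitochondrial ribosomal protein genes had 2 of 70 (mrps-35 and mrpl-18), RNA polymerase II and Mediator genes 2 of 48 (mdt-26 and mdt-22) and translation factors 1 of 39 (eif-3.E). Sm and SR splicing proteins had 1 of 15 (snr-1), cuticle collagens 3 of 173 (col-85, col-71 and col-54) and F-box genes 1 of 322 (fbxc-44). No gene was at a peak among 72 core histone genes (interval 0 to 4.99%), 140 neuropeptide genes (0 to 2.60%) and 31 major sperm protein genes (0 to 11.2%). The top peaks of replicate 1 alone touched 2 histone genes, those of replicate 2 none. None was at a peak either among 33 proteasome genes, 20 aminoacyl-tRNA synthetase genes, 20 vacuolar ATPase genes and the markers of muscle (23), intestine (24), neurons (29) and pharynx (13). Protein-coding genes at the other nuclear peaks of highest signal were F56G4.6 (signal 309.1), cux-7 (289.9) and W04C9.4 (232.6).

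The X chromosome carried more peaks than its length predicts, and chromosome V fewer. X held 151 of the 584 nuclear peaks (25.9%) where its length gave 103.2, a ratio of 1.46 (interval 1.26 to 1.68, adjusted p = 2.75e-06, exact binomial test). V held 75 peaks where its length gave 121.9, a ratio of 0.615 (interval 0.491 to 0.759, adjusted p = 2.75e-06, exact binomial test). The other ratios were 0.854 for I, 0.877 for II, 1.22 for III and 1.05 for IV, none of which passed the test. In the top peaks of replicate 1 the ratio was 1.40 for X and 0.598 for V, and in those of replicate 2 it was 1.28 and 0.673. X also holds 276 of the nuclear tRNA genes, more than the 78 on V or the number on any other chromosome. Peaks within 500 bp of a tRNA gene start numbered 128 on X, 3.10 times what length gives (interval 2.72 to 3.46). Among the 350 nuclear peaks away from tRNA genes, a split chosen after the data were seen, X held 23 where length gave 61.8. That is a ratio of 0.372 (interval 0.238 to 0.549, adjusted p = 1.02e-08, exact binomial test), the opposite direction to that of all peaks. In the same split chromosome III stood at 1.54 (adjusted p = 0.000528), IV at 1.31 (adjusted p = 0.0183) and V at 0.753 (adjusted p = 0.0266, exact binomial tests).

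**Figure D3:**
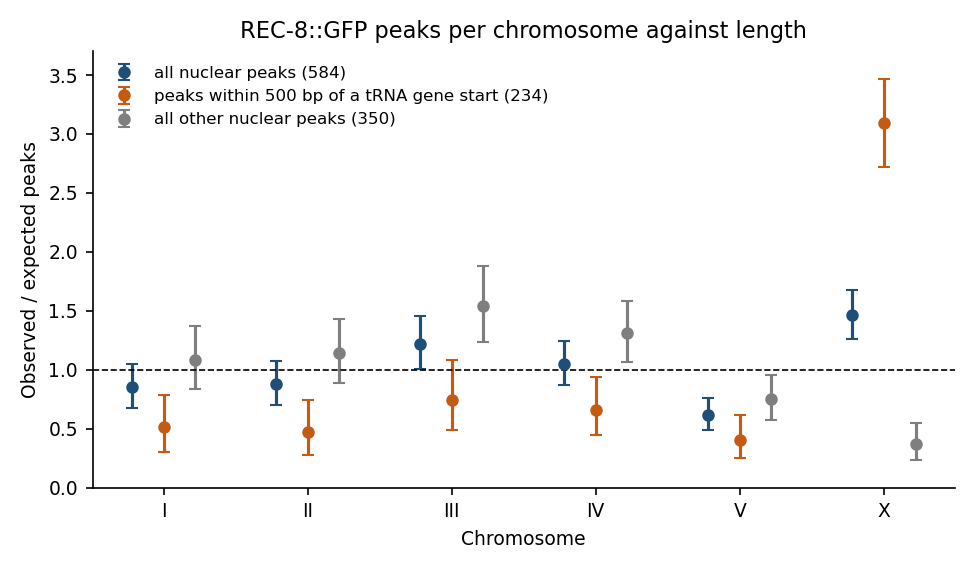
Observed over expected number of peaks on each nuclear chromosome, with exact 95% intervals, for all 584 nuclear peaks, the 234 within 500 bp of a tRNA gene start and the other 350, where the dashed line marks the number that length alone gives. On X the ratio is 3.10 for peaks at tRNA genes and 0.372 for the others.

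Along the chromosomes, whether peaks favoured the centres depended on the set of peaks taken. On the autosomes the central part (33.3% of the length) held 162 of 433 peaks (37.4%, interval 32.8 to 42.2, p = 0.0744, exact binomial test). That share was 39.4% in the top peaks of replicate 2 (p = 0.00703), 37.3% in those of replicate 1 (p = 0.0855), 44.0% in the 303 peaks of higher signal (p = 0.00217) and 38.2% on ce10 (p = 0.0363, exact binomial tests). On X it held 63 of 151 (41.7%, interval 33.8 to 50.02, p = 0.031, exact binomial test). The result for X did not pass in either replicate alone (p = 0.197 without replicate 1 and 0.187 without replicate 2, exact binomial tests). Set against the share of protein-coding genes in the central part, neither the autosomes (38.1% expected, p = 0.805) nor X (35.7% expected, p = 0.127) differed by the exact test.

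The sequence under the summits was rich in GC and often held the core of the B box, the element inside tRNA genes that recruits the RNA polymerase III machinery. GC content was 43.1% at summits and 36.5% in the flanks, a difference of 6.69 percentage points (SE 0.342, n = 606 peaks, permutation p = 1e-05, the smallest the test can give). That difference was 9.42 points at the 311 nuclear peaks with a tRNA, snoRNA or snRNA start near and 2.32 points at the 162 with only a protein-coding start near, a split chosen after the data were seen. The B box core GGTTCGA lay in 174 of 606 summit windows (28.7%) and in 13 left flanks (2.15%, adjusted p = 2.31e-40, exact McNemar test). Of these 174 windows, 156 were at the 311 nuclear peaks with a tRNA, snoRNA or snRNA start near. The GA repeat GAGAGA was in 20.8% of summits and 11.4% of left flanks (adjusted p = 2.16e-05, exact McNemar test). The GC box CCGCCC was in 10.1% and 3.14% (adjusted p = 5.92e-06, exact McNemar test). The E-box CATATG was less frequent at summits, at 1.82% against 4.29% (adjusted p = 0.0301), but not in the top peaks of either replicate alone (adjusted p = 0.253 and 0.11, exact McNemar tests). The T block and the E2F-like motif TTCGCGC did not pass the test (adjusted p = 0.0824 and 0.108, exact McNemar tests). In the top peaks of a replicate alone, the T block was less frequent in both replicates (adjusted p = 0.0487 in replicate 1 and 0.0143 in replicate 2), and the E2F-like motif was more frequent in replicate 1 (adjusted p = 0.0497, exact McNemar tests). Peaks simulated at tRNA genes also gave more B box cores, GA repeats and GC boxes than their flanks. The result for the B box core thus follows from peaks at tRNA genes, and such peaks can add to those for the GA repeat and the GC box. At the same 162 peaks the GC box was in 11.7%, which is 6.33 times its share of the left flanks (adjusted p = 0.00513) and 2.71 times that of the right flanks (adjusted p = 0.0507, exact McNemar tests). The E2F-like motif was in 9 of these summits, 3 left flanks (adjusted p = 0.292) and 0 right flanks (adjusted p = 0.0234, exact McNemar tests). The GA repeat passed against neither flank (adjusted p = 0.888 and 0.22, exact McNemar tests). Over all peaks the right flank held the GC box in 5.28% (adjusted p = 0.00293), and against it the E-box did not pass (adjusted p = 0.0962, exact McNemar tests).

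The replicates shared their top peaks far more often than chance. Of the 606 top peaks of replicate 1, 335 (55.3%, Wilson interval 51.3 to 59.2) had a summit within 100 bp of one of the 606 top peaks of replicate 2. For the nuclear peaks alone 317 of 585 were matched, where rotations matched a mean of 0.696 and at most 5. A peak within 100 bp was listed for 586 of the 606 reproducible peaks in replicate 1 and for 588 in replicate 2, at whatever rank. Across the 551 nuclear peaks with a match in both, Spearman's rho of the replicate signals was 0.418, a value across peaks, which are not independent replicates. These peaks were chosen by the signal of both replicates together, a choice that can lower rho. No line was identical between the lists of the replicates. All 606 reproducible peaks were the 606 highest peaks of the relaxed list of both replicates together.

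The gene that was tagged, rec-8 (IV:13349122-13353193, minus strand), had no reproducible peak within 2000 bp. The strongest relaxed peak of both replicates together in this stretch ranked 1017 of 18953 (signal 63.4, −log10 q 2.08), with its summit at 13348465, 657 bp past the 3′ end of the gene. Replicate 1 listed a peak close by at rank 324 (summit 13348421), whereas the strongest peak of replicate 2 in the stretch ranked 3322 and lay beyond the other end of the gene. The gene unc-119 (III:10902641-10908935), a common selection marker in worm transgenes, had no reproducible peak, and its strongest relaxed peak ranked 6550 (signal 34.8).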

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

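The test of the mitochondrial peaks was chosen after the result was seen. The 22 reproducible peaks on mitochondrial DNA stood out because they are signal outside the nuclear chromosomes, on which the chromosome comparisons rest. Their median signal was 2151, against 107.6 for nuclear peaks, and 19 of them exceeded the highest nuclear signal of 421.4. The peak of highest signal (8472, M:11559-12905) had its summit in ND5, and the next (8377, M:4147-5595) near the start of CYTB. Both genes encode proteins of the respiratory chain. Replicate 1 listed 21 mitochondrial peaks and replicate 2 listed 23, with highest signals of 4655 and 4182. The summits also lay at ND4, ATP6, ND2, COX1, ND3 and ND1, at the tRNA genes for threonine, histidine, lysine, serine and cysteine, and at both rRNA genes.

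A candidate explanation is the copy number of the mitochondrial molecule, present many times per cell, which would raise reads along all of it. The peaks covered 80.2% of the 13794 bp, in 9 distinct intervals, which goes with it. Signal was uneven, from 139 to 8472 over the summits, a ratio of 60.8 against 5.23 for nuclear peaks, and 4.33 between the highest summits of the intervals. The first of these ratios goes against even reads and the last does not. How the control entered the signal is unknown here, and a control would hold the same copies, so copy number and discrete binding sites cannot be told apart. The design names no second group, so no biological explanation was tested.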

How the results depend on the processing

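Of 427 alternative values for 55 results, 358 kept direction and side of the threshold or moved little. Where others did not, the cause was not tested unless stated. The direction turned in 30, of which only that of X was past the threshold both ways and 29 were past it in neither. The 358 kept values include those of the 10 lists with no gene at a peak. Their ratio stayed at 0 in most settings and had little room to change. An alternative set of the 303 reproducible peaks of higher signal has that size by construction. In it the autosomal centres held 44.0% of peaks (p = 0.00217), the X centre 39.8% (p = 0.214), chromosome IV stood at 0.877 and the T block ratio was 0.655 (adjusted p = 0.0354, exact tests). In each replicate alone the X centre held 38.6%, the autosomal centres 37.3% to 39.4%, the chromosome III ratio was 1.17 to 1.25 (past the threshold in replicate 2), and the ratios of the motifs were 0.524 to 0.64 for the E-box, 0.712 to 0.754 for the T block (past the threshold in both) and 1.62 to 3 for the E2F-like motif (past it in replicate 1). With the ce10 files the autosomal centres held 38.2% (p = 0.0363) and the X centre 40.3% (p = 0.0819, exact tests). With protein-coding genes as the expectation, chromosome II stood at 0.773 and III at 1.27 (adjusted p = 0.0215 for both), the autosomal centres held 37.4%, below the 38.1% expected, and the X centre held its 41.7% with p = 0.127 (exact tests).

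Matching of the replicates moved with its definition: 62.9% of peaks shared at least 1 bp, 44.6% of summits lay within 50 bp, and lists of 303 and 1212 peaks matched in 62.4% and 42.8%. Spearman's rho was 0.5001 for summits within 50 bp. Rotations in place of Fisher's test left 1 list with fewer genes at peaks, with a chemoreceptor ratio of 0.338 (adjusted permutation p = 0.276). In a window of 250 bp the ribosomal protein ratio was 2.72 (adjusted p = 0.41, exact test), as their summits lay farther from annotated starts. In 100 bp of sequence the T block ratio was 0.594 (adjusted p = 0.0132, exact test). With the right flank as control, chosen after the data were seen, the E-box ratio was 0.5 (adjusted p = 0.0962, exact test). Against starts with no peak the T block ratio was 0.787, and the E2F-like ratio was 2.92 (adjusted p = 0.0143 and 0.000212, exact tests). Leaving out peaks at tRNA genes, an alternative chosen after the data were seen, turned the X ratio to 0.372 and moved I to 1.08, II to 1.14, III to 1.54 and IV to 1.31. The 6 other changes were lists that passed only under an alternative, heat shock and respiratory genes with more peaks and F-box genes with fewer. Depth is unknown, so its effect on the number of peaks was not tested.

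The other 25 turns were in lists that passed in no setting of theirs. Ratios fell to 0 in the set of 303 peaks for the meiotic, germline, translation factor, Sm and SR, and RNA polymerase II and Mediator lists, and to 0.79 for collagens. With a window of 250 bp they were 0 for the meiotic, germline, Sm and SR, and collagen lists. With a window of 1000 bp they were 0.936 for the meiotic list, 1.33 for the proteasome and 1.001 for microRNAs. The meiotic ratio was 0 with outermost 5' ends only, the rRNA ratio 0 on nuclear chromosomes only, also by rotations, and the microRNA ratio 2.41 by rotations of all or of nuclear chromosomes. In each replicate alone ratios were 0 to 3.64 (meiotic), 0 to 2.91 (translation factors), 0 to 3.78 (Sm and SR), 0 to 2.06 (histones), 0.424 to 0.982 (collagens) and 0.921 to 1.35 (microRNAs).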

Other observations

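The tests of the X chromosome along its whole length, of the low number of other peaks on X, of retention at transcribed genes, of X without the peaks at tRNA genes, of X against autosomal tRNA genes, of copies against each other, of isotypes and of the right flank were chosen after the results were seen. tRNA genes on X were at a peak more often than those on autosomes. On X 155 of 276 tRNA genes (56.2%, interval 50.1 to 62.1) were at a peak, against 117 of 336 on autosomes (34.8%, interval 29.7 to 40.2; two-sided Fisher's exact test, p = 1.53e-07). The shares were 51.4% and 33.3% in the top peaks of replicate 1, and 47.5% and 34.2% in those of replicate 2 (p = 8.03e-06 and 0.000935, Fisher's exact tests). Among tRNA genes with no other tRNA gene start within 1000 bp the shares were 64.8% on X and 32.5% on autosomes (p = 1.02e-09, Fisher's exact test), so tRNA genes that share a peak with a neighbour do not account for the difference. By isotype, cysteine tRNA genes were at a peak in 11 of 13 cases, alanine in 22 of 34 and histidine in 3 of 20.

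Peaks at protein-coding starts lay mostly upstream of the annotated start. Of the 166 summits with a protein-coding start and no listed RNA gene start within 500 bp, 136 (81.9%) were upstream, and the median offset was -152 bp. Annotated starts in worms are often trans-splice sites, so the distance to the true start of transcription is unknown. No expected share upstream was computed. The GC box was in 11.7% of the 162 nuclear ones among them and in 1.85% of their left and 4.32% of their right flanks (adjusted p = 0.00513 and 0.0507, exact McNemar tests), so that result depends on the flank. Peaks at snoRNA genes were frequent at the top of the ranking, with 19 of the 50 nuclear peaks of highest signal and 11 of the last 184. Those at tRNA genes numbered 13 and 52 in the same ranks, and no test of this was made.

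More peaks on X than its length predicts: a candidate explanation is the number of tRNA genes on X. Without the peaks at tRNA genes the X ratio was 0.372, so the excess lay in the peaks at tRNA genes. Their number is not the only difference, as 56.2% of tRNA genes on X and 34.8% on autosomes were at a peak. Leaving out these peaks removes both differences, so it cannot tell the number of tRNA genes from their higher share at peaks. A gain of called signal along all of X would raise the other peaks too. In the relaxed list outside the reproducible set the X ratio against length was 0.808 (interval 0.78 to 0.837). But X held 14.3% of those peaks, which is below its 17.7% of the length and above its 13.7% of protein-coding genes. The direction thus depends on the expectation, and the relaxed list does not decide whether there was such a gain. The low number of other peaks on X is not accounted for by fewer protein-coding genes there, since against the share of those genes the ratio was 0.481 (interval 0.308 to 0.709). What sets it stays open, and no biological explanation was tested, as the series has no second group.

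Peaks at tRNA genes: reads shared between identical copies could place peaks at copies that have no signal of their own. Of 143 nuclear tRNA genes with a sequence found once, 30.8% (interval 23.3 to 39.0) were at a peak, the outcome set down against shared reads as the whole cause. But a summit within 500 bp of such a gene can belong to a neighbouring tRNA gene that has copies. Such neighbours were not left out here, and nearly identical sequences were not examined, so shared reads are not excluded as the whole cause. Genes with an identical copy were at a peak in 48.6% of 469 cases (p = 0.000171, two-sided Fisher's exact test), which is the outcome set down for shared reads. For this excess shared reads and signal of their own cannot be told apart, since the files hold no reads. Retention of any highly transcribed gene in an immunoprecipitation, whatever the antibody, may add peaks at the same genes. The 17.3% of ribosomal protein genes at a peak goes with it. The lack of reproducible peaks at 72 histone genes decides nothing, as it did not differ from other protein-coding genes (adjusted p = 0.966, Fisher's exact test). Replicate 1 alone touched 2 of them. Among other lists, 4 of 59 chaperone genes (adjusted p = 0.061, Fisher's exact test) and 0 of 33 proteasome genes (interval 0 to 10.6%) were at a peak. Neither list passed that test, so they do not decide it either. Without an untagged or tag-only library, retention cannot be told apart from binding of REC-8.

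Other hypotheses were tested on the same peaks. If the peaks at protein-coding starts rested on a B box, its core would be frequent there. It was in 3.70% of those summits, 1.85 percentage points more than in the left flanks (normal-approximation interval -1.77 to 5.47). This argues against the exact core GGTTCGA under most of these peaks, but not against RNA polymerase III elements that lack it. Of the 311 nuclear peaks with a tRNA, snoRNA or snRNA start near, only 156 held the core. If snoRNA genes with a B box of their own were the ones at peaks, the core would be near them more often. It lay within 200 bp of the start in 16.7% of 66 snoRNA genes at a peak and in 5% of 280 with none (p = 0.00263, two-sided Fisher's exact test), which is consistent with this but leaves most snoRNA genes at a peak without the core. Of 340 nuclear tRNA genes with no reproducible peak, 55% had a summit of the relaxed list within 100 bp of their start, against 3.65% in rotations (permutation p = 0.001, the smallest 1000 rotations can give), consistent with weaker signal below the threshold. Isotypes differed by no more than chance could give, with a permutation p of 0.0757 within X and autosomes, which does not show that their shares are equal.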
